A study of Coturnix japonica with 36 samples.

How the data were processed

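Brains of 12 Japanese quail were cut in sections of 200 µm, and the 3 regions were taken with a punch of 1.25 mm, per the labels' protocols. Gonads were removed or inspected at 2.5 weeks of age. Total RNA was depleted of ribosomal RNA, and the 12 libraries of each region were pooled and run over the 4 lanes of 1 NextSeq500 chip in paired-end reads of 75 nt, per the labels' protocols. Region and chip therefore coincide, while the 4 groups of a region share a chip.

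The deposited values are whole-number counts per component, 1 column per library, with no header. The names have the form that de novo transcript assemblers give, and the labels' protocols speak of an assembly without naming the assembler. BWA, Trimmomatic, DESeq2, edgeR, limma and the chicken build galGal5 are named in the submitters' processing notes, with no role, order or version. How reads were assigned to components, and whether strand was used, is not given in the sources used here. Reads from a gene and an antisense partner, or from near-identical copies, may then share a component or be divided over several, and 1 gene may appear as several components. Each file listed the same components, of which 1273 had no read in any library, and the names fell into 531244 assembly clusters. No pair of libraries held identical counts.

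Component names were looked up in a RefSeq gene table of the Japanese quail assembly, and 0 matched. Chromosomes and gene names are thus not used here. The comparison of genes on the Z chromosome between the sexes, the tests of the gene lists fixed before the data were examined, and the rule for named genes could not be run. In place of named genes, at most 2 identifiers per direction are given, with the rule stated beside them. It keeps the part of the rule set before the data were examined that needs no gene name (past the threshold, no overlap, at least 1 CPM, largest change). Asking for all 3 regions was added afterwards.

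Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each region, components passing filterByExpr (minimum count 10) were kept, scaled by TMM and fitted with 1 mean per group over all 12 libraries. Contrasts were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The contrasts were male minus female in intact and in testosterone-treated birds, Ovx+T minus intact females, Cx+T minus intact males, male minus female over both hormone states, and the interaction. All 36 libraries entered 1 fit for differences between regions, with the bird as a block, because each bird gave all regions. The pairing by bird was checked on 21801 components. Deviations from the group mean correlated between regions of the same bird with a median of 0.366 (range 0.0784 to 0.581, 34 pairs), and between birds of the same group with a median of -0.185, across components, which are not independent replicates. Correlations between birds lean below 0 because deviations within a group sum to 0.

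The failed library stayed in the fits because they were set before the data were examined. Its TMM factor of 10.9 rests on few reads. The same fits were tested on simulated data in which 67 components were changed by 0.8 on the log2 scale, 67 by 1.5 and 66 by 3. The simulated counts varied independently between components, without levels shared by a bird, so the shares below may differ in the real data. In POM the simulated sex comparison over both hormone states made 26 calls on unchanged components, which were 16.5% of its calls. It made 34 such calls (23.4%) without the failed library. The numbers were 11 (8.66%) in VMN and 11 (9.17%) in TnA. For the sex comparison of treated birds the share was 18.9% in POM, 10% in VMN and 8.79% in TnA. For that of intact birds it was 19.8% in POM, 6.74% in VMN and 6.02% in TnA. Calls near the threshold are thus less certain than the adjusted p of 0.05 implies in POM, and to a smaller degree in VMN and TnA.

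Alternatives were RLE size factors, no filter on low counts, only the libraries compared, the first letter of the bird name or 1 surrogate variable (sva 3.50.0) as covariate, DESeq2 1.42.0, limma 3.58.1 (voom with duplicateCorrelation) for the 36-library fits, and each replicate left out. After the data were seen, these were added: leaving out the failed and dominated libraries, DESeq2 without the failed library, counts summed per assembly cluster, a minimum mean of 1 CPM, and each bird left out of the 36-library fits. The dominant set was defined, after the data were seen, as components above 20000 CPM in a library and above 10 times their median. The set of components restricted to females and its limits were also chosen then. CPM values in the text scale the counts by all reads of a library. Floors and reads cover counting error only, since the reads carry no molecular identifiers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.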

Results

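RNA was measured in 3 brain regions of 12 adult Japanese quail, a bird in which testosterone activates male sexual behaviour in adulthood. The regions were the medial preoptic nucleus (POM), the ventromedial nucleus (VMN) and the nucleus taeniae of the amygdala (TnA). Each bird gave 1 library per region, so the set held 36 libraries. The birds formed 4 groups of 3. Intact females and intact males had a sham operation and empty implants. Ovariectomised females (Ovx+T) and castrated males (Cx+T) carried 2 testosterone implants of 20 mm each from 6 weeks of age, and all birds were killed at 12 weeks. No group was gonadectomised without testosterone, so each treatment comparison joins the loss of the gonads with the implants. Replicates were separate birds, as the bird names in the titles show. The counts were made per assembled transcript component, a cluster of sequences that an assembly of the reads treats as 1 gene, and every library listed the same components. The files do not pair the component names with gene names, and 0 of them were found in the reference gene table used here, so the results below describe components and not named genes.

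Read totals lay between 10442521 and 40082871 in 35 of the libraries, with a median of 28855884. The library of intact male 3 (bird R18) in POM held 1742 reads over 999 components. It carries almost no information, and the POM counts are therefore also given without it. A set of 4 components, each of which passed 20000 CPM (counts scaled by the total reads of a library) in a library and 10 times its own median, took a median of 0.0821% of the reads of these 35 libraries. Its share was above 20% in 5 libraries. These were intact female 1 in POM with 29.4%, Ovx+T female 3 in POM with 61.6%, Cx+T male 3 in POM with 56.6%, intact male 2 in VMN with 22.6% and intact male 3 in TnA with 27.3%. These 5 libraries are called dominated libraries below. Simulated data had the same components, depths and spread, but the components varied independently, without levels shared by a bird. There the comparison of intact males with intact females in VMN recovered 92.4% of components changed by 3 on the log2 scale. It recovered 28.4% of those changed by 1.5 and 4.48% of those changed by 0.8.

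**Figure D1:**
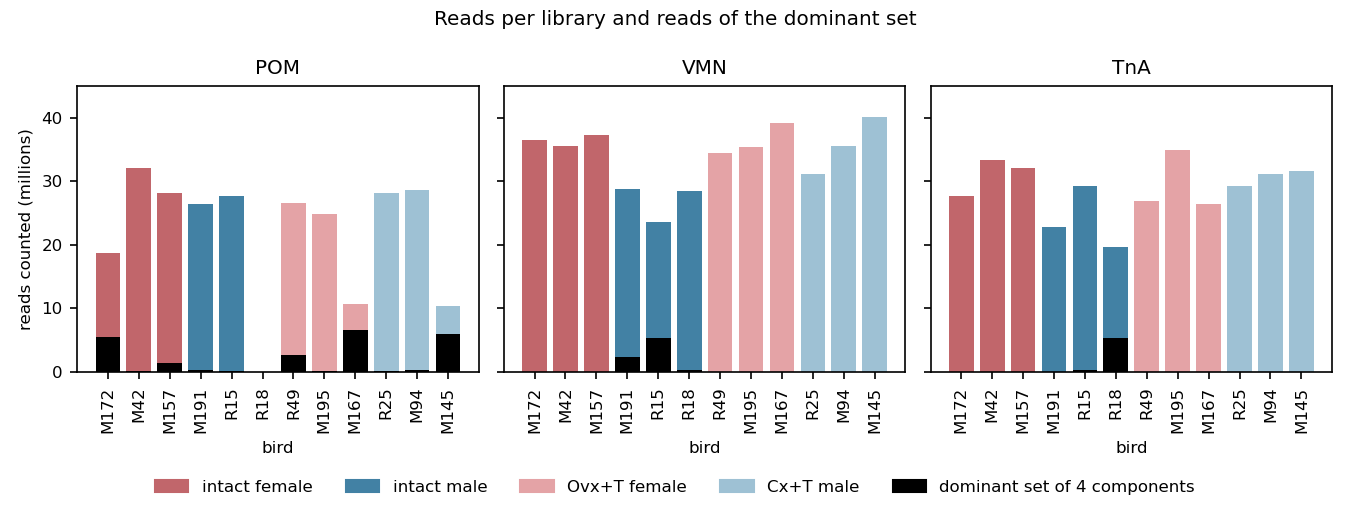
Reads counted per library (vertical axis) for the 12 birds of each region, with the reads of the 4 components of the dominant set in black and the other reads coloured by group. Intact male R18 in POM has 1742 reads, and the dominant set takes up to 61.6% of a library (M167 in POM).

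The 3 regions differed in a large part of the components. In a fit of all 36 libraries with the bird as a block (edgeR, 108761 components tested), 14170 components differed between POM and VMN, 37455 between POM and TnA and 36346 between VMN and TnA. Of the differences between POM and VMN, 6134 were higher in POM and 8036 in VMN. With RLE size factors the split was 6553 against 6305. Each region was sequenced as 1 pool on its own chip, so these counts hold the difference between chips as well as between regions.

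The first question was how gene activity differed between intact males and intact females. In POM, 412 components were higher in males and 201 were higher in females (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 80699 components tested, n = 3 birds per group). The median change of the male-higher components was 1.2 on the log2 scale, with quartiles of 0.995 and 1.68. Of the 201 female-higher components, 47 had no read in the intact male libraries of the region, 1 of which is the failed one. In VMN, 282 components were higher in males and 101 in females of 100736 tested. The male-higher components had a median log2 change of 1.09, and 59 of the female-higher components had no read in intact males. TnA gave 22 components higher in males and 68 higher in females of 84395 tested, and 36 of the latter had no read in intact males. With no read on the male side a fitted change is not a size. With such components set to their bound against 3 reads over the intact male libraries, the female-higher components had a median log2 change (male minus female) of -2.27 in POM, -4.00 in VMN and -4.54 in TnA. Without the failed library, POM had 367 components higher in males and 177 in females, and without the failed and the dominated libraries 223 and 131. Without intact male 1 and without intact male 2, each of which leaves 1 usable intact male beside the failed one, the POM total of 613 fell to 149 and 190, and without intact male 1 it split into 73 higher in males and 76 higher in females. With a minimum mean of 1 CPM, TnA had 44 higher in males and 30 higher in females. Against 22 and 68, the TnA counts higher in males and in females were 1 and 58, 7 and 58, and 2 and 51 without intact females 1, 2 and 3. The TnA total of 90 was thus 59 without intact female 1 and 53 without intact female 3, and the VMN total of 383 was 239 and 238 without intact females 1 and 2. With the first letter of the bird's name (M or R) as a covariate, the totals were 57 in TnA and 199 in VMN. The letter is partly tied to sex, since all intact females carry M while intact males R15 and R18 carry R.

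The same comparison between Cx+T males and Ovx+T females asked which sex differences are present when both sexes carry the same implants. POM had 342 components higher in males and 199 higher in females. The counts were 327 and 164 in VMN and 47 and 81 in TnA. Male-higher components had a median log2 change of 1.35 in POM, 1.37 in VMN and 2.05 in TnA. These medians, like those of the other comparisons, cover called components only. In simulated data this comparison in TnA recovered 1.49% of components changed by 0.8 and 23.9% of those changed by 1.5. Smaller changes were thus seldom called, and the medians lean high. RLE size factors gave a TnA split of 23 higher and 81 lower, which moved the share of male-higher calls from 36.7% to 22.1%. Without the failed library POM had 212 higher in males and 162 higher in females, and without the failed and the dominated libraries together 78 and 114. In VMN, leaving out any 1 of the 6 libraries turned the majority. The counts higher in males and in females were then 30 and 90, 39 and 110, and 32 and 104 without Ovx+T females 1, 2 and 3, and 70 and 112, 96 and 99, and 75 and 107 without Cx+T males 1, 2 and 3. With no filter on low counts it also turned (681 and 1067), while it stayed with DESeq2 (336 and 199) and with only the libraries compared in the fit (839 and 419). The POM total of 541 fell to 116 without Ovx+T female 1 (25 higher in males and 91 in females), 218 without Ovx+T female 2 (58 and 160), 256 without Cx+T male 1 (128 and 128) and 263 without Cx+T male 2. In TnA the counts higher in males and in females were 9 and 68, 11 and 73, and 8 and 61 without Ovx+T females 1, 2 and 3, and 18 and 65, 28 and 62, and 13 and 60 without Cx+T males 1, 2 and 3. With a minimum mean of 1 CPM the TnA split turned to 53 and 29. Which sex had more calls in treated birds is therefore not settled in any region.

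These 2 sex comparisons used different birds and can be set side by side without a shared control. Both come from 1 fit per region with a shared filter and estimate of spread, so their lists are not fully independent. The numbers expected of independent lists leave this out. In POM, 104 components were called higher in males in both, against 1.75 that independent lists of these lengths would share, and 75 were called higher in females in both, against 0.496. In VMN the numbers were 75 against 0.915 and 83 against 0.164. In TnA they were 1 against 0.0123 and 58 against 0.0653. Among all components called in intact birds, 86.1% in POM, 90.3% in VMN and 88.9% in TnA had the same sign in the testosterone-treated birds. On mean log2 CPM, 1 of the 20 signed splits of the 6 treated birds gave a share as large as the real one in POM, 3 of 20 did in VMN and 4 of 20 in TnA. The real shares on that scale were 86.1%, 89.8% and 88.9% and the highest others 80.9%, 90.3% and 92.2%, and 20 splits are too few for a share of splits under 0.05.

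Taking both hormone states together gave the largest counts, from 6 males and 6 females. In POM, 1406 components were higher in males and 362 in females. VMN had 1155 and 168. In TnA 866 were higher in males, 85.7% of its 1011 calls. The median log2 change of the male-higher components was 1.02 in POM, 0.985 in VMN and 1.19 in TnA. Across the 3 regions, 378 components were called in every region out of 71849 tested in all of them, and all 378 kept their direction, 294 higher in males and 84 higher in females. The regions come from the same birds, so this overlap holds the birds' own levels too. Between different birds, 71 components higher in intact males in POM were also higher in Cx+T males in VMN, against 1.51 for independent lists, 75 were lower in both, against 0.341, and 5 went opposite ways. Intact birds in VMN and treated birds in POM shared 91 higher and 73 lower. Pairings with TnA shared few male-higher components. Treated birds in TnA shared 6 higher and 60 lower with intact birds in POM, and 5 and 63 with those in VMN. Intact birds in TnA shared 4 and 58 with treated birds in POM, and 4 and 58 with those in VMN. Without the failed library, POM had 1041 components higher in males and 298 in females. Without the failed and the dominated libraries, the counts were 632 and 189 in POM, 940 and 180 in VMN and 538 and 142 in TnA. The POM total of 1768 was 937 without intact male 1, 911 without intact male 2 and 1065 without Ovx+T female 1. The VMN total of 1323 was 836 and 818 without Cx+T males 2 and 3, 787 and 784 without Ovx+T females 1 and 3, 852 without intact female 1 and 877 without intact male 1. The TnA total of 1011 was 463, 476 and 550 without intact females 1, 2 and 3, 480, 469 and 592 without Ovx+T females 1, 2 and 3, and 444 and 404 without Cx+T males 1 and 3. With the first letter of the bird's name (M or R) as a covariate, the TnA total was 425. Because the letter is partly tied to sex, this drop cannot tell an effect of sex from one of the letter. DESeq2 gave a POM total of 54, and 1055 without the failed library. With a minimum mean of 1 CPM the totals were 1027, 799 and 567 in POM, VMN and TnA, and with no filter on low counts the VMN total was 2210. In every setting and with every library left out, more of the calls over both hormone states were higher in males in all regions. With no filter on low counts the majority was narrow in TnA, with 757 higher in males and 708 in females. In VMN it was 1350 against 860.

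**Figure D2:**
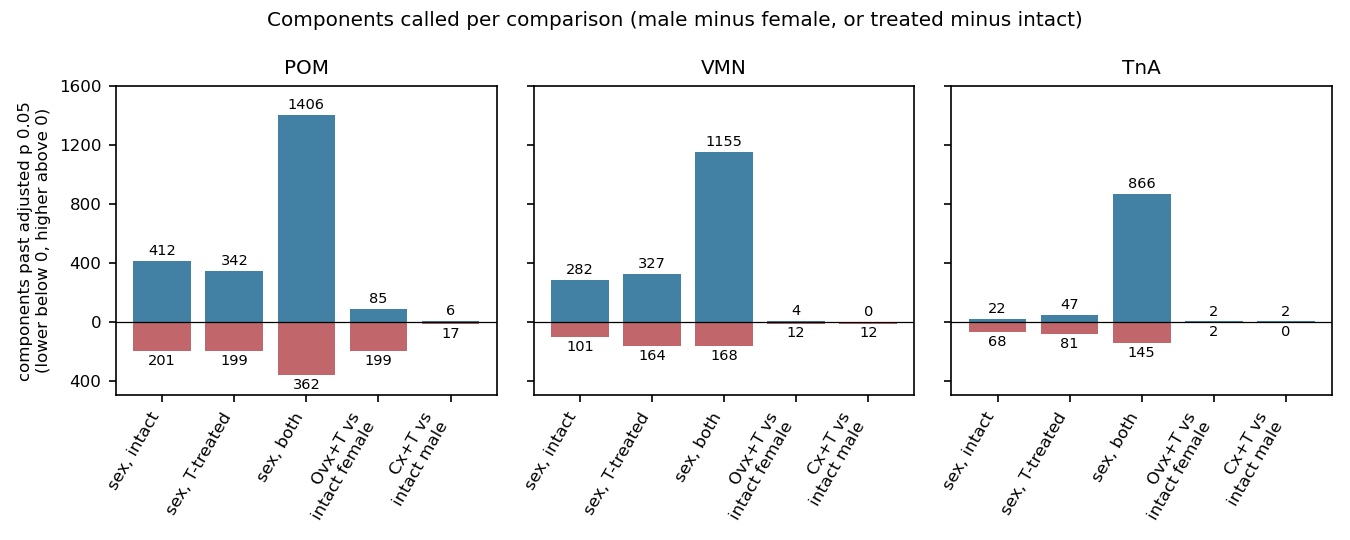
Components past an adjusted p of 0.05 (edgeR) in each comparison, with those higher in males, or in treated birds, above 0 and those lower below 0. The sex difference over both hormone states gives 1406 higher in POM, 1155 in VMN and 866 in TnA, while Cx+T against intact males gives at most 17 in either direction in any region.

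The identifiers named here are the 2 with the largest mean log2 change in each direction among those past the threshold in all regions, with no overlap between the sexes in usable libraries and a mean of at least 1 CPM in the higher sex. This rule left 3 of the 294 components called higher in males in every region, and 33 of the 84 higher in females. TR242525|c3_g1 was higher in males. In VMN it had 1.78 CPM ± 0.527 in males and 0.531 CPM ± 0.0614 in females (SD, n = 6 each), with a log2 difference of 1.75, a standard error of 0.173 and an adjusted p from edgeR of 1.38e-05. TR210779|c10_g3 had 1.83 CPM ± 0.436 in males and 0.802 CPM ± 0.163 in females in VMN, with a log2 difference of 1.22, a standard error of 0.173 and an adjusted p from edgeR of 0.000741. In TnA the adjusted p from edgeR was 0.0195 for TR242525|c3_g1, with 1.67 CPM in males. It was 0.0172 for TR210779|c10_g3, with 1.31 CPM in males. TR236324|c4_g1 was higher in females. It had 313 CPM ± 25.5 in females and 0.361 CPM ± 0.373 in males in VMN, from 68283 and 77 reads, with a log2 difference (male minus female) of -10.22, a standard error of 0.278 and an adjusted p from edgeR of 8.75e-14. TR232883|c1_g5 had 13.1 CPM ± 4.03 in the 6 POM libraries of females and 0 reads in the 5 usable POM libraries of males, which makes it at least 531-fold higher in females against a floor of 3 reads over those 5 libraries. It was not absent from males elsewhere, with 3 male and 3211 female reads in VMN and 2 and 2497 in TnA.

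The sex difference was uneven in size. Among components with a log2 CPM above 3, and after the median of these components was set to 0, the band between 0.5 and 1.2 held 365 components higher in males and 155 higher in females in POM. It held 247 and 45 in VMN and 298 and 49 in TnA. Beyond 1.2 the numbers were 13 and 37 in POM, 14 and 13 in VMN and 24 and 9 in TnA. Before centring, the TnA median was -0.156 for these abundant components and 0.0548 for all tested ones, so the TnA numbers depend on the centring. The 383 components in the male-higher band of intact birds in VMN had a median of 0.46 in the treated birds, and the 126 in the female-higher band a median of 0.02. In POM these medians were 0.49 for 462 components and -0.09 for 371, and in TnA 0.35 for 471 and -0.13 for 106. Of the male-higher band, 86.8% in POM, 68.9% in VMN and 78.1% in TnA kept their sign in the treated birds. Of the female-higher band, 66.6%, 46% and 58.5% did. The limits of the band were chosen after the data were seen.

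**Figure D3:**
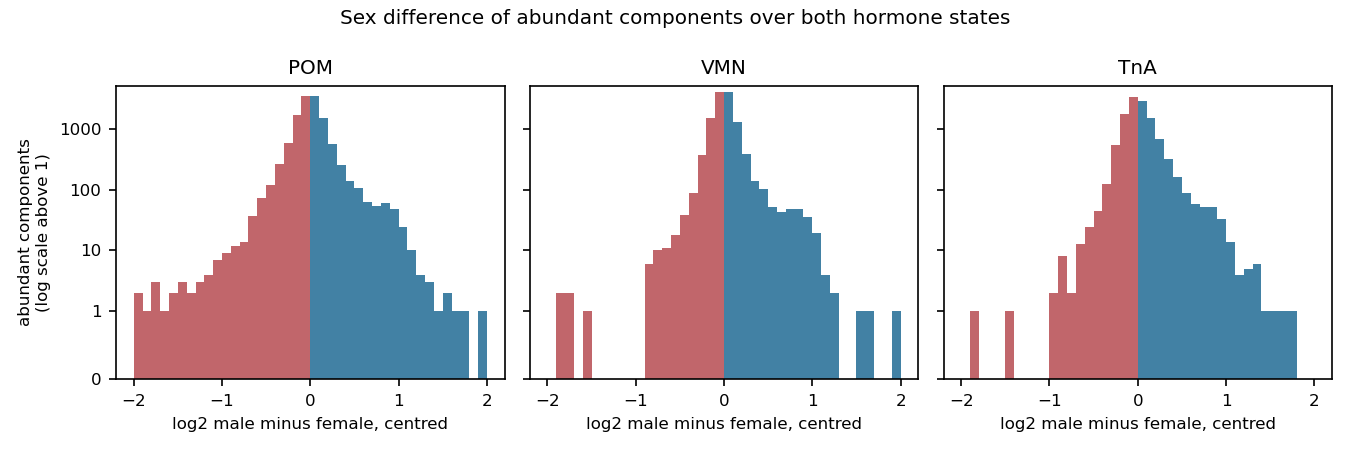
Number of abundant components (log2 CPM above 3, vertical axis on a log scale above 1) by their log2 difference, male minus female over both hormone states, centred on the median and drawn between -2 and 2 in steps of 0.1, with male-higher components in blue and female-higher ones in red. The side higher in males has a shoulder between 0.5 and 1.2, with 247 components in VMN against 45 on the other side.

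A group of 76 components was read in all 18 female libraries and had a mean level in the 17 usable male libraries under 2% of the female mean, with at least 100 reads in females. The mirror definition gave 0 components restricted to males. The number depends on the limits, with 31 components at 5 times that minimum of reads, 67 at a male level under 1% and 85 without the dominated libraries. Of the 76, 25 had no read in any usable male library. The summed level of the 76 in VMN was 595 CPM ± 52.6 in intact females, 609 CPM ± 22.7 in Ovx+T females, 0.487 CPM ± 0.277 in intact males and 1.58 CPM ± 0.863 in Cx+T males (SD, n = 3 each). Over the libraries, the lowest female value was 222.5 CPM and the highest male value was 3.63 CPM. When the group was defined again without the bird measured, the lowest female value was 222.7 CPM and the highest male value 3.73 CPM, so the sex label of all 35 usable libraries matched. In 924 divisions of the 12 birds into 6 and 6, counted in both directions, the highest number of restricted components in any other division was 3.

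**Figure D4:**
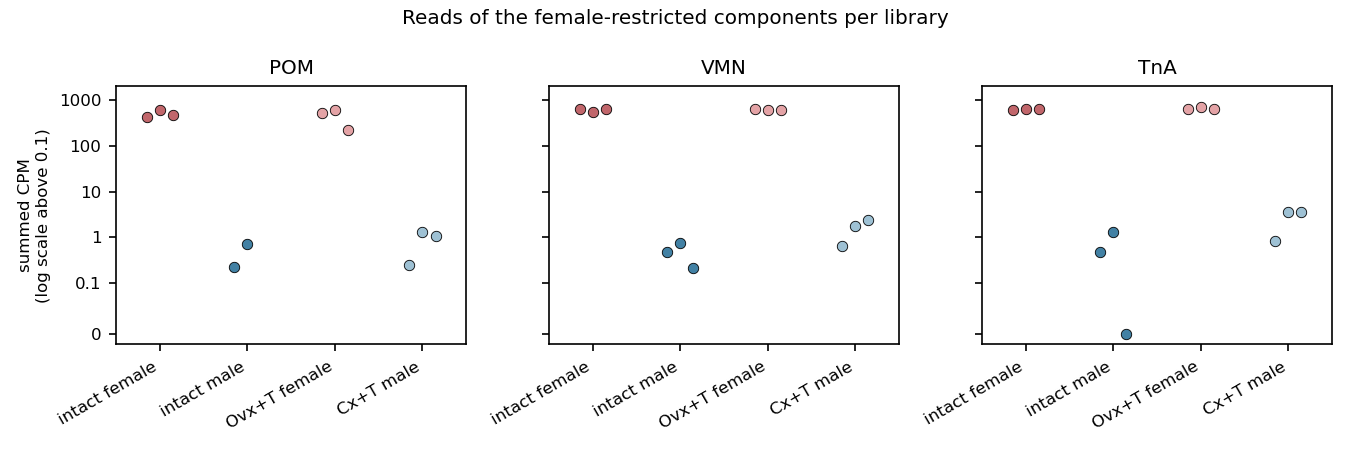
Summed CPM of the 76 female-restricted components in each of the 35 usable libraries by group, on a log scale above 0.1. Female libraries lie at or above 222.5 CPM and male libraries at or below 3.63 CPM in every region.

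Ovx+T females were compared with intact females to ask what the removal of the ovary together with testosterone changed. In POM, 85 components were higher and 199 lower in Ovx+T females, out of 80699 tested (edgeR). The median log2 change was 1.94 for the higher and -1.68 for the lower components, with the 1 higher and the 3 lower components that lacked any read on the other side set to their bound. VMN had 4 higher and 12 lower components, and TnA had 2 higher and 2 lower. Simulated data with no treatment change gave 1 call in POM (3 without the failed library), 0 in VMN and 2 in TnA for this comparison. Of the components called in POM and tested elsewhere, 80.5% had the same sign in VMN and 74.7% in TnA of the same birds. In POM of the males, which are other birds, 66.9% had the same sign between Cx+T and intact. That was 54.1% of the components higher in Ovx+T females and 72.4% of the lower ones. Of the components called in POM without the failed library, 71.5% had the same sign in males. For the 16 components called in VMN the share in males was 12.5%, and for the 4 called in TnA it was 75%. Without the failed library, 73 components were higher and 183 lower in POM, and without the failed and dominated libraries 31 and 83. The POM total of 284 was 100 without Ovx+T female 1 and 163 without Ovx+T female 2. In VMN the total of 16 was 0 without intact female 1, 3 without intact female 2, and 7, 7 and 8 without Ovx+T females 1, 2 and 3 (with 4 and 6 of the 7 higher without females 1 and 2), and in TnA the total of 4 (edgeR) was 0 without intact female 1 or Ovx+T female 1, 1 without intact female 2 or 3, and 7 without Ovx+T female 2. With RLE size factors the split was 4 against 7 in VMN and 2 against 1 in TnA. DESeq2 gave 67 higher and 31 lower in VMN, so the direction of the few VMN calls depends on the tool. Without the dominated library, TnA had 8 higher and 4 lower.

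Cx+T males differed from intact males in fewer components than any sex comparison in the same region. POM had 6 higher and 17 lower in Cx+T males. VMN had 0 higher and 12 lower, with 8097 components at an unadjusted p under 0.05 in either direction, and DESeq2 called 12 higher and 178 lower. TnA had 2 higher and 0 lower, with 4234 components at an unadjusted p under 0.05, and DESeq2 called 12 higher and 9 lower. Simulated data with no treatment change gave 0 calls in POM (8 without the failed library), 4 in VMN and 1 in TnA for this comparison. With RLE size factors, which moved the median of all POM components by 0.127 on the log2 scale, the POM split was 4 higher and 7 lower. Without the failed library POM had 4 higher and 16 lower. Without the failed and the dominated libraries POM had 5 higher and 6 lower, and TnA 0 higher and 2 lower, with 4748 TnA components at an unadjusted p under 0.05 in edgeR. In VMN, where intact male 2 is the dominated library, the total of 12 was 138 without it (17 higher and 121 lower), 36 without intact male 3 and 4, 3 and 6 without Cx+T males 1, 2 and 3. The POM total of 23 was 13 without intact male 2 and 42 without Cx+T male 1, and the TnA total of 2 was 22 without intact male 1 (6 higher and 16 lower) and 0 without intact male 2 or Cx+T male 1.

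Whether the treatment acted differently in the 2 sexes was tested as an interaction of sex and treatment. In POM, 63 components passed, 40 with a higher change in males and 23 with a higher change in females. VMN had 47, of which 20 had a higher change in males, and TnA had 5, of which 4 did. With RLE size factors, which moved the median of all POM components by 0.15, the split was 60 against 18 in POM and 18 against 39 in VMN. Without the failed and the dominated libraries the POM split turned to 5 against 13, and that of VMN was 33 against 72. The majority also turned in POM without intact male 1 (10 against 19), Ovx+T female 1 (17 against 21), Ovx+T female 2 (16 against 28) or Cx+T male 1 (17 against 24), in VMN without intact female 1 (18 against 9), intact female 2 (13 against 8) or Cx+T male 2 (34 against 24), and in TnA without intact male 1 (8 against 11). With 1 surrogate variable as covariate the totals were 26 in POM and 2 in VMN, and with the first letter of the bird's name the VMN total was 18 (12 against 6). DESeq2 gave 0 in POM, with 88 components at an unadjusted p under 0.05, 99 there without the failed library, and 230 in VMN. The POM total was 46 without the failed library (28 against 18), 29 without intact male 1, 38 without Ovx+T female 1, 41 without Cx+T male 1, 103 without intact female 1 and 100 without intact female 3. The VMN total was 105 without intact male 2, 29 without Cx+T male 1, 27 without intact female 1 and 21 without intact female 2. The TnA total was 9 and 3 without intact females 1 and 2, 19 and 10 without intact males 1 and 2, 3 and 2 without Ovx+T females 1 and 2, and 3 and 23 without Cx+T males 1 and 2.

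Differences between the regions in these effects were few. In the 36-library fit with the bird as a block, the sex difference over both hormone states differed between regions in 10 components of 108761, the effect of Ovx+T in females in 60 and the effect of Cx+T in males in 18. A shift common to a whole chip cancels in these tests. Without the pairing of regions by bird, the numbers were 7, 8 and 0, and for the last of these 5898 components had an unadjusted p under 0.05 in edgeR. limma with voom gave 0, 16 and 0, with 1370 and 3482 components at an unadjusted p under 0.05 for the first and the last. Without Ovx+T female 1, the effect in females differed in 17 components. The effect in males differed in 378 components without intact male 1, 51 without intact male 2, 32 without intact male 3, 29 without intact female 2, 51 without intact female 3, 49 without Ovx+T female 2 and 7 without Cx+T male 2. The sex difference differed in 20 components without intact female 2, 21, 16 and 25 without intact males 1, 2 and 3, 32 and 27 without Ovx+T females 2 and 3, and 33 and 25 without Cx+T males 2 and 3.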

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

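All tests of explanations and all splits of the birds in this part were chosen after the results were seen, while the interaction tests and the tests between regions were fixed before the data were examined.

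The treatment differed between the sexes by the interaction test in 63 components in POM, 47 in VMN and 5 in TnA. For POM, 1 of the 40 splits drawn gave as many calls, the real one, and the highest other had 50. The share is under 0.05, but it is the smallest that 40 splits allow and rests on 63 against 50, and the real count was 46 without the failed library, 29 without intact male 1, 38 and 44 without Ovx+T females 1 and 2, 41 without Cx+T male 1 and 18 without the failed and the dominated libraries. For VMN it was also 1 of 40, with 47 against 3 as the highest other. In all regions these splits shuffled the labels of all groups, which mixed the sexes and put the sex difference into the spread. They therefore do not test the interaction alone and cannot exclude chance for it. At an unadjusted p under 0.05 in edgeR, the real VMN fit had 9663 components and a relabelled fit had 10666. The counts also depend on the model, since 1 surrogate variable left 26 in POM and 2 in VMN. The first letter of the bird's name left 18 in VMN. DESeq2 gave 0 in POM, 99 there without the failed library and 230 in VMN. For TnA 2 of 40 splits gave as many calls, with a highest of 11 against the real 5, so chance cannot be excluded there.

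The effects differed between regions in 10 components for sex, 60 for Ovx+T in females and 18 for Cx+T in males. Relabelled fits were run on every 10th component. There the real labels gave 2, 5 and 6 components and the highest of the other labellings gave 2, 3 and 18. As many as the real number came from 2, 1 and 3 of 21 labellings, the real one included, so chance cannot be excluded for sex or for Cx+T in males. For Ovx+T in females the share is under 0.05, but it is the smallest that 21 labellings allow and rests on 5 components against 3, and the full count of 60 was 8 without the block, 16 with limma and 17 without Ovx+T female 1. For the differences between POM and VMN, POM and TnA, and VMN and TnA, the real values on these components were 1452, 3837 and 3746. The highest others were 3, 1 and 25. Each time 1 of 21 labellings reached the real value, the smallest share that 21 labellings allow. The share is under 0.05 and the real values lie far above the others, which argues against chance.

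For the sex difference over both hormone states, 1 of 40 splits reached the real number in each region. That share is under 0.05 but is the smallest that 40 splits allow. These splits too shuffled the labels of all groups. They argue against chance in the group labels as a whole and do not test sex alone. The real values were 1768, 1323 and 1011 in POM, VMN and TnA, and the highest others 296, 71 and 5. The comparisons of 3 birds with 3 have 10 splits, too few for a share under 0.05. In POM the real and the highest other counts were 613 and 91 for sex in intact birds, 541 and 31 for sex in treated birds, 284 and 14 for Ovx+T and 23 and 17 for Cx+T. In VMN they were 383 and 43, 491 and 7, 16 and 1, and 12 and 7. In TnA they were 90 and 1, 128 and 2, 4 and 0, and 2 and 2, and in the last of these 3 of the 10 splits gave as many.

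More components were higher in males than in females over both hormone states, and 76 were restricted to females with 0 restricted to males. A scaling shift common to all components is argued against by the band between 0.5 and 1.2. After centring, that band held at least 2.35 times as many male-higher as female-higher components in every region. A shift that varies with abundance was not tested. In TnA the median before centring was -0.156 for the abundant components and 0.0548 for all tested ones. The ratio there depends on the centring. The failed and dominated libraries are argued against by the fits without them, where at least 77% of the calls in each region were higher in males. A candidate explanation is the number of sex chromosomes, since male birds carry a pair of Z chromosomes and females a Z and a W, and the 76 components restricted to females would then lie on W. This cannot be told apart from other differences between the sexes, because the component names matched no gene in the table used here and chromosomes were not analysed.

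In POM, 284 components differed between Ovx+T and intact females. In the fit without the dominated and failed libraries, 284 of the 284 kept their sign. Their median log2 change in the called direction was 1.78 there, with a lower quartile of 1.3. The libraries left are among those that chose the list, so this cannot decide whether the dominated libraries are the cause. The fit without them called 114 components, and 90 were called in both fits. Levels that belong to single birds in all regions stay open, because at least 74.7% of the components had the same sign in the other regions of the same birds, which a treatment effect shared by the regions would also give. In males, on mean log2 CPM of the usable libraries, 68.3% had the same sign, against at most 66.5% in the other signed splits of the 5 libraries. That check was limited to usable libraries after a first value with the failed library had been seen.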

How the results depend on the processing

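Leaving out the failed and dominated libraries, DESeq2 without the failed library, sums per assembly cluster, the minimum mean of 1 CPM and leaving out birds in the 36-library fits were chosen after the data were seen, and the other alternatives before. The number of components restricted to females, 76, was 31 at 5 times the minimum of reads, 67 at a male level under 1% and 85 without the dominated libraries, all chosen after the data were seen. A count is called moved when it changed by over 1.5 times, and the cause was not tested unless given. The planned 36-library fit with no filter on low counts was not run. The Z-linked tests, the gene lists and the named genes were not run because no component name matched the gene table used here.

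In this paragraph the comparisons are sex in intact birds, sex in treated birds, Ovx+T in females, Cx+T in males, sex over both hormone states, and interaction. With RLE size factors 20 of 21 counts stayed within the limit, and Cx+T in POM gave 11. With no filter on low counts, 16 of 18 counts rose by over 1.5 times, and the other 2 rose within that limit. In POM these were 1244 (sex in intact birds), 1234 (sex in treated birds), 1091 (Ovx+T), 624 (Cx+T) and 695 (interaction). In VMN all 6 counts rose, in the order given, to 1528, 1748 (0.283% of those tested), 1078, 1245, 2210 and 1561. In TnA they were 769, 864, 835, 560 and 663 for all but sex over both hormone states. With only the libraries compared in the fit, Cx+T in POM gave 71, VMN gave 203 and 1258 (1.45% of those tested) for sex in intact and treated birds and 128 for Ovx+T, and TnA gave 47 for Ovx+T and 6 for Cx+T.

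With the first letter of the bird name as covariate, VMN gave 199 for sex in intact birds, 7 for Cx+T and 18 for the interaction, and TnA gave 57 for sex in intact birds and 425 over both hormone states. With 1 surrogate variable, POM gave 1 for Cx+T and 26 for the interaction, VMN gave 295 (0.293% of those tested) for sex in treated birds, 0 for Ovx+T, 1 for Cx+T and 2 for the interaction, and TnA gave 12 for Ovx+T, 1 for Cx+T and 9 for the interaction. With no filter on low counts the majority turned in POM for sex in treated birds (545 against 689) and the interaction (334 against 361), and in VMN for sex in treated birds (681 against 1067) and Ovx+T (636 against 442). Fitted with only the libraries compared, Ovx+T in VMN split 70 against 58. The VMN interaction turned with the first letter (12 against 6), 1 surrogate variable (2 against 0) and a mean of 1 CPM (12 against 6). In POM the surrogate variable was -0.957 in the failed library and between 0.0668 and 0.107 in the others.

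DESeq2 with the failed library gave 18, 15, 17, 0, 54 and 0 in POM in the order given, with 2 against 16 and 0 against 15 for sex in intact and treated birds. Without that library DESeq2 gave 604, 399, 298, 32, 1055 and 99. Beside edgeR without it as well, Cx+T (32 against 20) and the interaction (99 against 46) moved and the other 4 counts did not. In VMN DESeq2 gave 654 for sex in intact birds, 98 for Ovx+T, 190 for Cx+T and 230 for the interaction, and in TnA 147 and 211 for sex in intact and treated birds, 64 for Ovx+T, 21 for Cx+T and 58 for the interaction. Without the failed and dominated libraries the POM counts were 354, 192, 114, 11, 821 and 18, VMN gave 138 for Cx+T and 105 for the interaction, and TnA gave 12 for Ovx+T. Summed per assembly cluster, Cx+T in POM gave 9, Ovx+T in VMN 4 and the interaction in TnA 11. With a mean of at least 1 CPM, which tests fewer components, POM gave 6 for Cx+T, 1027 for sex over both hormone states and 32 for the interaction, VMN gave 10 for Ovx+T, 3 for Cx+T, 799 for sex over both hormone states and 18 for the interaction, and TnA gave 82 for sex in treated birds, 0 for Ovx+T, 0 for Cx+T, 567 for sex over both hormone states and 3 for the interaction.

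With each replicate left out, the counts in POM ran from 149 to 598 for sex in intact birds, 116 to 428 for sex in treated birds, 100 to 325 for Ovx+T, 13 to 42 for Cx+T, 911 to 2000 for sex over both hormone states and 29 to 103 for the interaction. In VMN they ran from 238 to 366, 0.108% to 0.18% of the tested components, 0 to 14, 3 to 138, 784 to 1372 and 21 to 105, and in TnA from 53 to 110, 69 to 90, 0 to 7, 0 to 22, 404 to 753 and 2 to 23. Where a group was left with 1 usable library, that library was assumed to vary like the other groups.

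Among differences between regions, the fit with no replicate block gave 8 components for Ovx+T and 0 for Cx+T, against 60 and 18 with the pairing by bird, and the block moved no other count by over 1.5 times. limma with voom gave 0 for sex, 16 for Ovx+T and 0 for Cx+T. With each bird left out the counts ran from 10 to 33 for sex, 17 to 88 for Ovx+T and 7 to 378 for Cx+T, and from 11437 to 13643 between POM and VMN, 33216 to 38160 between POM and TnA and 34135 to 36661 between VMN and TnA. In VMN the log2 difference between the sexes stayed between 1.66 and 1.82 for TR242525|c3_g1, 1.15 and 1.32 for TR210779|c10_g3 and -10.7 and -9.99 for TR236324|c4_g1 with each replicate left out. For TR232883|c1_g5 it stayed between -10.7 and -9.26. What depth limits was not compared between regions, and usable libraries held as few as 10442521 reads.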

Other observations

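The tests in this part were all chosen after the results were seen.

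In 1 intact male, bird R18, 49 of 32836 components with at least 1000 reads in all had at most 0.1% of their reads in that bird and more in each of the others, while no other bird had more than 3 such components of its own. R18 has no usable POM library, so a component read almost only in POM could meet this limit for that reason. The summed level of the 49 was at most 21.6 CPM in the usable libraries of that bird and at least 316 CPM in every usable library of the other birds. Of the set's reads, 89.1% lie in its 6 most abundant components, so these sums say little about the rest. The VMN library of R18 held 617 reads of the set, where the lowest level among the other VMN libraries would give 18859. That gap cannot test shallow libraries as the cause, because the set was chosen for few reads in that bird. In depth, that library held 28531537 reads. The VMN library of intact male 2 held 23539378, and the set had 708 CPM there. A loss of quality across the libraries of R18 stays open. The share of components low in that bird alone, 0.149%, is the same count that prompted the observation and counts near-complete absence only. No biological explanation was tested, and with 1 bird none can be tied to a group.

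Within each region, deviations of a library from its group mean were correlated best, among the birds of its group, with those of the same bird in each other region for 34 of 35 libraries, across components. The median log2 change in VMN and TnA of the components called between Ovx+T and intact females in POM, in the direction of POM, was 0.78 and 0.62.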
